A study of Drosophila melanogaster with 12 samples.

How the data were processed

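RNA was measured in Malpighian tubules of Drosophila melanogaster females of 3 lines, SU26 and SU58 from Sweden and ZI418N from Zambia, and of the F1 hybrids SU26xSU58, SU26xZI418N and SU58xZI418N. Per the labels, the flies were 6 days old and kept at 20 °C with 14 h of light and 10 h of dark, poly-A RNA was selected, and paired reads of 125 bases were sequenced on an Illumina HiSeq instrument. There were 12 libraries, 2 per genotype, which the labels call biological replicates. Per the file headers, the values the authors deposited are counts per gene, beside a gene identifier, a CG number, a chromosome and a length, and no normalization or filter had been applied to them as far as the values show. The aligner, the counting tool, the genome build and the treatment of reads that map to several genes are not given in the sources used here. The values were checked to be whole numbers. The series also concerns the expression of each parental allele in hybrids, and counts per allele were not analysed here.

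The files hold 13919 genes. Of these, 13749 identifiers were found in the name table, 146 were named through their CG number and 24 have no name. No library had a count for 1015 genes. The chromosome arm in the files equals that in the Ensembl BDGP6 annotation for 13746 of 13749 genes. Coordinates and shared exons come from that annotation, whose build may differ from the authors' build. Total counts per library ranged from 30834175 to 43479929 and precision at the levels of most named genes is set by the spread between the 2 libraries of a genotype rather than by counting error. The 2 libraries of each genotype were checked not to be copies of each other, with a mean chi-square per gene from 13.7 to 122.8. CPM values use library sizes scaled by the TMM factors.

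Genes were filtered with edgeR's filterByExpr, which left 9302 genes, and libraries were scaled with TMM factors. A mean per genotype was fitted with edgeR 4.0.16 in R 4.3.3, with 6 residual degrees of freedom and 3.08 prior degrees of freedom. The common biological coefficient of variation was 22.5% and the median per gene 14.4%. Contrasts were tested by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05. The contrasts were the 3 pairs of parental lines, ZI418N against the mean of SU26 and SU58, each F1 against the mean of its parents on the log2 scale, each F1 against both parents for expression outside their range, the 3 pairs of F1s, and the mean of the hybrids against the mean of the parents. For expression outside both parents the larger of the p-values against each parent was used, with the same sign required. A mean of parents in CPM lies above the mean on the log2 scale, so genes above the log2 mid-parent are set beside the parents' mean in CPM. The position of an F1 between its parents was computed from the fitted log2 fold changes, and per replicate from log2 CPM with a prior count of 2, for genes that differed between the parents by test and by at least 2-fold. Principal components were computed from log2 CPM of the tested genes.

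Gene lists were tested with camera of limma 3.58.1 with a preset correlation between genes of 0.01, and again with an estimated correlation. The lists were V-ATPase subunits, tubule ion and water transport, organic solute and metal transport, hormone and amine receptors, cytochrome P450, insecticide-linked cytochrome P450, glutathione S-transferases, UDP-glycosyltransferases, antimicrobial peptides and peptidoglycan recognition, purine, tryptophan and eye pigment metabolism, heat shock proteins and Turandot, metallothioneins and antioxidant enzymes, cytosolic ribosomal proteins, oxidative phosphorylation, the proteasome, the circadian clock, genes with African against non-African expression differences in earlier studies, tubule principal and stellate cell markers, gut digestive enzymes, fat body, eggshell and germ line, muscle, hemocytes, and neurons and photoreceptors. These gave 125 tests, adjusted together. Of 26 lists written, that of male accessory gland and testis had 1 tested member and was not tested. Lists share members: the insecticide-linked P450 genes are part of the P450 list, Cyp6g1 is also in the African list, GstS1 is in the antioxidant list, and salt, Uro, Lkr and Prip are in several lists. The member nos of the eggshell and germ line list was not found by name.

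Genes were named by a rule. It took the 6 largest rises and falls of each pair of parental lines with an adjusted p under 0.05, a mean of at least 10 CPM and no overlap between the libraries of the lines, up to 3 members per list by lowest adjusted p, 5 rises and 5 falls for ZI418N against the Swedish mean and for each test of F1s, and always fiz, MtnA, Cyp6g1 and CHKov1. The text describes list members only where at least 3 passed or the list test passed. Exceptions are lists or libraries described by single genes chosen after their values were seen (osk, yl, CycB, bru1, AttD, Vm26Aa, Cp18, Cp15). The comparisons, the lists, the rule for names and the first set of alternatives were chosen before the data were examined. Those alternatives were DESeq2's size factors in edgeR, no filter on low counts, DESeq2 1.42.0 as the test, the replicate number as a block, fits restricted to the libraries compared, counts summed per genotype, other minimum folds between parents, and leaving out each library in turn. Where leaving out a library leaves 1 library in a genotype, that library is assumed to vary like the others. A pair of alternatives was added after seeing the data. In 1, SU58 replicate 1 and SU26xZI418N replicate 2, the libraries with the most eggshell or ovary transcripts, were both left out. In the other, the level of salivary gland markers (their mean log2 CPM) was added as a covariate.

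The tests were tried on simulated data, negative binomial counts with the library sizes, mean levels and spread per gene of these libraries and changes put into 200 genes. For ZI418N against SU26, 50.7% of 2-fold and 84.8% of 4-fold changes but 6% of 1.5-fold changes were recovered, and 1.1% of calls were false. For expression outside both parents 40.3% of 2-fold and 75.8% of 4-fold changes were recovered. For hybrids against parents 77.6% of 2-fold changes were recovered and 9% of calls were false. Of 20 random lists, the list whose genes were raised 1.5-fold was recovered and 0 of the others were called. Simulated genes were drawn independently, so this trial does not bear on correlation between the genes of a list. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.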

Results

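Gene expression was measured by RNA sequencing in the Malpighian tubules, the excretory and osmoregulatory organ of insects, of female Drosophila melanogaster aged 6 days. The tubules came from 3 parental lines and their 3 F1 hybrids. SU26 and SU58 are lines from Sweden and ZI418N is a line from Zambia, and the hybrids were SU26xSU58, SU26xZI418N and SU58xZI418N. Each of the 6 genotypes had 2 libraries, described by the labels as biological replicates, so that n = 2 for every mean below unless another n is given. The summed gene counts ranged from 30834175 in SU58 replicate 2 to 43479929 in SU26xSU58 replicate 1, and between 10762 and 11139 genes per library had at least 1 count. The most abundant gene, Mur18B, took from 3.47% to 5.51% of the counts. Levels are given in CPM, the counts of a gene scaled to library size, as mean ± SD, and log2 fold changes with an approximate standard error (SE). This SE is the absolute log2 fold change divided by the square root of the F statistic of its test. For genes near the limit of counting in a genotype it is only a rough guide to precision. Adjusted p-values of single genes are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over the 9302 genes tested.

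Libraries of the same genotype resembled each other least in SU26xZI418N. The correlation across genes of log2 CPM between the replicates of a genotype was 0.95 in SU26xZI418N and lay between 0.981 and 0.99 in the other genotypes (genes are not independent replicates). The highest correlation with another genotype was 0.98 for SU26xZI418N replicate 1, 0.988 for SU26xSU58 replicate 1 and 0.982 for SU58xZI418N replicate 2. For these libraries it exceeded that with their own replicate (0.95, 0.986 and 0.981). SU26xZI418N replicate 2 carried transcripts of the female germ line that its replicate 1 had at far lower levels. The germ plasm gene osk stood at 111 CPM in replicate 2 and 1.75 CPM in replicate 1, the vitellogenin receptor gene yl at 145 and 3.92 CPM, and CycB, a B-type cyclin, at 282 and 4.51 CPM. SU58 replicate 1 carried vitelline membrane transcripts of the eggshell. Vm26Ab stood at 68.1 CPM against 0.0636 CPM in SU58 replicate 2 and Vm26Aa at 118 CPM against no count. Other libraries carried such transcripts at lower levels. In SU26 replicate 1 the eggshell transcripts Cp18 and Cp15 stood at 13.4 and 6.44 CPM, against 0.403 CPM and no count in replicate 2. In SU58xZI418N replicate 2 osk, yl and CycB stood at 4.15, 7.43 and 11.6 CPM, against 0.254, 0.33 and 0.839 CPM in replicate 1. The first principal component held 33.5% of the variance and separated the Swedish lines from ZI418N. The hybrids of ZI418N lay between them, except SU26xZI418N replicate 2, which lay beyond ZI418N.

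**Figure D1:**
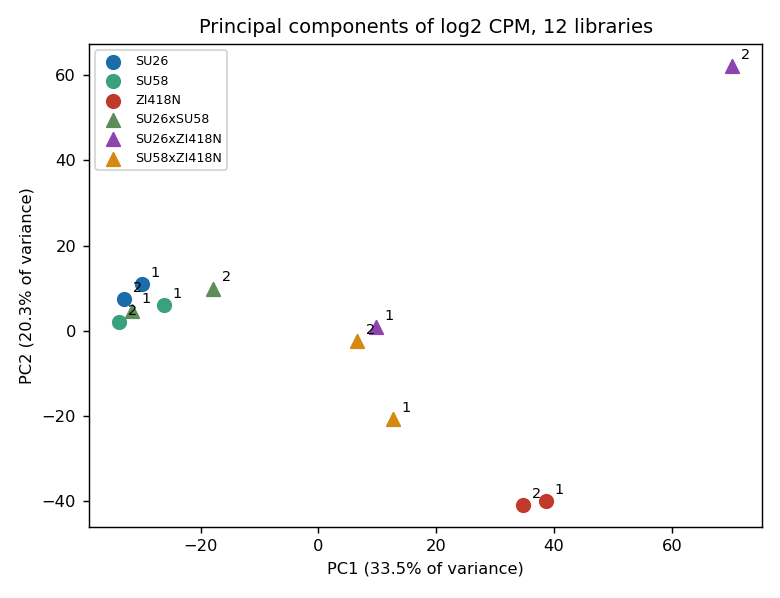
Principal components of log2 CPM over 12 libraries, with PC1 (33.5% of the variance) on the horizontal and PC2 (20.3%) on the vertical axis; circles are parental lines, triangles are hybrids, and the digit beside each symbol is the replicate. SU26xZI418N replicate 2 lies at 70.2 on PC1 and 62.2 on PC2, and its replicate 1 at 9.7 and 0.9.

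The contrast of SU58 with SU26 asked how expression differs between lines of the same population. Several genes were expressed in SU58 and near the limit of counting in SU26. CG6184 (FBgn0038725) stood at 38.3 ± 1.47 CPM in SU58 and 0.0784 ± 0.0294 CPM in SU26, a log2 fold change of 8.89 ± 0.56 (adjusted p = 3.07e-05). CG1695 was 346-fold higher in SU58 (54.3 ± 3.48 against 0.15 ± 0.0725 CPM), plx was 180-fold higher (75.1 ± 4.7 against 0.41 ± 0.113 CPM) and tinc was 61-fold higher (22.9 ± 0.658 against 0.375 ± 0.123 CPM). In the other direction Jhe, which encodes juvenile hormone esterase, was 102-fold lower in SU58 (0.235 ± 0.0277 against 24.1 ± 3.77 CPM). CG11155 was 42.3-fold lower (3.78 ± 0.131 against 160 ± 8.25 CPM, adjusted p = 5.83e-08), CG12910 was 23.3-fold lower and CG7968 was 20.2-fold lower. The rule also named Marf1, Srg2, CG4269 and Vm26Ab, whose calls were each lost in at least 3 alternatives. Marf1 stood at 46.7 ± 0.139 CPM in SU58 and 0.377 ± 0.167 CPM in SU26, and its adjusted p of 0.0269 passed 0.05 without any 1 of the 4 SU26 and SU58 libraries (at most 0.162). Srg2 and CG4269 stood at 26.8 ± 31.8 and 19.6 ± 18.1 CPM in SU26 and below 1 CPM in SU58, and without SU58 replicate 1 or 2 neither passed (adjusted p up to 0.135 and 0.0672 over the alternatives). Srg2 did not pass without SU26 replicate 1 either. Vm26Ab (adjusted p = 0.0344) was carried by SU58 replicate 1 alone, as given above, and its adjusted p ranged from 1.69e-06 to 0.946 over the alternatives, with 0.946 without that library. Its call was also lost without any 1 of the SU26 or ZI418N libraries. CG6184 lies at 3R 19652369 to 19657866 on the minus strand and CG11155 at 4 1126602 to 1137919 on the plus strand in the Ensembl annotation of BDGP6.

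Of the gene lists fixed beforehand, the proteasome and the respiratory chain were lower in SU58 than in SU26. Of 34 proteasome genes tested, 27 were lower and 0 higher (30 and 0 when adjusted over the list alone), among them Rpt5 (75.6 ± 1.3 against 118 ± 3.47 CPM), and camera placed the list below the other genes (adjusted p = 1.67e-08; adjusted p = 0.596 with an estimated correlation). Of 70 genes of oxidative phosphorylation 32 were lower and 1 higher (40 and 1 adjusted over the list alone), with a median log2 fold change of -0.3 (adjusted p = 6.42e-07; adjusted p = 0.74 with an estimated correlation). Their cytochrome c oxidase gene cype stood at 189 ± 1.19 against 280 ± 9.43 CPM. Of 26 transporters of organic solutes and metals 9 were lower and 2 higher (11 and 3 adjusted over the list alone; list adjusted p = 0.00104; adjusted p = 0.596 with an estimated correlation). They included Indy, a citrate transporter (78.8 ± 8.81 against 240 ± 3.22 CPM), and the ABC transporter gene MRP (492 ± 14.2 against 1220 ± 203 CPM). The principal cell markers numbered 9, of which 0 were higher and 2 lower (0 and 3 adjusted over the list alone; list adjusted p = 0.274), salt (2040 ± 189 against 5640 ± 655 CPM) and the urate oxidase gene Uro, whose call ended without SU26 replicate 2 or SU58 replicate 1 (adjusted p = 0.0115, at most 0.113 over the alternatives).

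Detoxification genes differed in both directions between the Swedish lines. Of 71 cytochrome P450 genes 22 were higher and 13 lower in SU58 (25 and 15 adjusted over the list alone), and the list as a whole did not stand apart (adjusted p = 0.123). Among the 8 insecticide-linked P450 genes 4 were higher and 0 lower, also when adjusted over the list alone (list adjusted p = 0.00152; adjusted p = 0.313 with an estimated correlation). Cyp6a8 (FBgn0013772) was 12.6-fold higher in SU58 (989 ± 193 against 78.7 ± 21 CPM, adjusted p = 6.32e-05), and Cyp12d1-p was 1.89-fold higher. Of 29 UDP-glycosyltransferases 12 were higher and 4 lower (13 and 7 adjusted over the list alone), with Ugt35C1 at 925 ± 41.7 against 260 ± 54.8 CPM (list adjusted p = 0.0302; adjusted p = 0.508 with an estimated correlation; up to 0.0589, lost without SU26xZI418N replicate 1 or 2 and with no filter on low counts). Of 29 glutathione S-transferases 10 were lower and 4 higher (13 and 4 adjusted over the list alone; list adjusted p = 0.00679; adjusted p = 0.579 with an estimated correlation). GstS1 was 19.9-fold lower (2.46 ± 0.781 against 49.4 ± 19.3 CPM) and GstE6 2.09-fold higher.

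Stress and immune genes were lower in SU58, and for the heat shock list this rested on a single SU26 library. Of 18 genes for antimicrobial peptides and peptidoglycan recognition 8 were lower and 2 higher (10 and 2 adjusted over the list alone; list adjusted p = 0.00374; adjusted p = 0.219 with an estimated correlation). The attacin gene AttC stood at 0.0134 ± 0.019 CPM in SU58 and 1.36 ± 0.521 CPM in SU26, and the attacin gene AttD at 21.4 CPM in SU26 replicate 1 and 0.807 CPM in replicate 2. Of 18 heat shock and Turandot genes 0 were higher and 2 lower, Hsp22 and the co-chaperone gene stv (0 and 5 adjusted over the list alone; list adjusted p = 0.00479; adjusted p = 0.782 with an estimated correlation). Hsp22, whose exons lie fully within those of another gene, lost its call without SU58 replicate 1 (at most 0.0522 over the alternatives), and stv lost it without SU26 replicate 2 or either SU58 library (at most 0.148). Without SU26 replicate 2, where the list summed to 4434 CPM against 1624 CPM in replicate 1, its adjusted p was 0.483. Of 18 metallothionein and antioxidant genes 7 were lower and 1 higher, as when adjusted over the list alone, with the peroxiredoxin gene Prx2 at 231 ± 12.7 against 562 ± 27.3 CPM (list adjusted p = 0.0035; adjusted p = 0.342 with an estimated correlation). Of 15 eggshell and germ line genes 3 were higher, the vitelline membrane genes Vm26Aa, Vm26Ab and Vml, all carried by SU58 replicate 1 (5 higher and 4 lower adjusted over the list alone; list adjusted p = 0.813, with a median of -0.12, a mean of 0.07 and the test pointing down). The list summed to 421.3 CPM in that library and 27.5 CPM in SU58 replicate 2.

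In all, 1639 of 9302 genes differed between SU58 and SU26, 750 higher and 889 lower in SU58, and 644 of them by at least 2-fold. The count fell to 492 (284 higher and 208 lower) without SU58 replicate 1, 579 (298 and 281) without SU58 replicate 2 and 791 without SU26 replicate 2. It was 618 (360 higher and 258 lower) when SU58 replicate 1 and SU26xZI418N replicate 2 were both left out.

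The contrast of ZI418N with SU26 set the African line against a European line. Among genes with a mean of at least 10 CPM, those most raised in ZI418N were led by spz, which encodes the Toll ligand Spätzle, at 42.1 ± 5.7 CPM against 0.284 ± 0.168 CPM in SU26 (log2 fold change 7.16 ± 0.58, adjusted p = 6.18e-05). The D-amino acid oxidase gene Daao2 was 63.2-fold higher (21.7 ± 1.13 against 0.344 ± 0.12 CPM), CG31683 was 41.8-fold higher and CG31997 was 28.1-fold higher. Cyp6a16 was 12.3-fold higher (596 ± 39.4 against 48.3 ± 4.55 CPM, adjusted p = 3.9e-07), and Karl, a lipocalin gene, was 11.1-fold higher. Among the genes lower in ZI418N were Jhe (0.169 ± 0.0425 against 24.1 ± 3.77 CPM), CG17636 (1.01 ± 0.414 against 132 ± 42.4 CPM) and mthl9 of the methuselah receptor family (1.01 ± 0.181 against 102 ± 10.5 CPM, adjusted p = 5.03e-08). CG14957 was 64.6-fold lower and Npc2b, of the sterol-binding Niemann-Pick type C2 family, was 55.2-fold lower. Srg2 had 0 counts in both ZI418N libraries and 26.8 ± 31.8 CPM in SU26, at least 637-fold lower against a floor of 3 counts over the group (0.0421 CPM), or at least 102-fold without SU26 replicate 1. Its adjusted p was 0.00325, and it ranged from 2.6e-09 to 0.0916 over the alternatives.

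Energy metabolism and protein turnover genes were lower in ZI418N than in SU26. Of 70 genes of oxidative phosphorylation 54 were lower and 1 higher (62 and 2 adjusted over the list alone), with a median log2 fold change of -0.5 (list adjusted p = 1.7e-12; adjusted p = 0.596 with an estimated correlation). ND-B14, of complex I, stood at 53.3 ± 3.33 against 96.1 ± 4.06 CPM. Of 34 proteasome genes 30 were lower and 0 higher (33 and 1 adjusted over the list alone; list adjusted p = 5.48e-10; adjusted p = 0.579 with an estimated correlation), with Prosbeta1 at 51.4 ± 1.83 against 85.4 ± 0.752 CPM. Antimicrobial and recognition genes were lower in 12 of 18 and higher in 2 (13 and 2 adjusted over the list alone; list adjusted p = 0.00259; adjusted p = 0.219 with an estimated correlation). The list was not called against SU58 (2 higher and 3 lower, adjusted p = 0.63) or the Swedish mean (adjusted p = 0.0603). Its median was 11.7 and 2.59 CPM in SU26 and 0.312 and 0.429 CPM in ZI418N. Its sum was higher in ZI418N, at 331.1 and 395.6 against 272.9 and 182.5 CPM. Metallothionein and antioxidant genes were lower in 7 of 18 and higher in 0 (8 and 0 adjusted over the list alone; list adjusted p = 4.31e-05; adjusted p = 0.219 with an estimated correlation), with the extracellular superoxide dismutase gene Sod3 at 28.2 ± 0.425 against 56.9 ± 0.9 CPM. Transporters of organic solutes and metals were lower in 8 of 26 and higher in 3 (9 and 3 adjusted over the list alone; list adjusted p = 0.0234; adjusted p = 0.74 with an estimated correlation), with Indy at 86.4 ± 4.52 and the ABC transporter gene Mdr49 at 351 ± 22.8 CPM in ZI418N against 573 ± 21.7 CPM in SU26.

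Stellate cell markers were higher in ZI418N. Of 9 markers 5 were higher and 0 lower, as when adjusted over the list alone (list adjusted p = 0.00672; adjusted p = 0.622 with an estimated correlation). The aquaporin gene Prip stood at 212 ± 6.65 against 110 ± 4.93 CPM, the chloride channel gene ClC-a at 527 ± 38.4 against 257 ± 45.9 CPM and the leucokinin receptor gene Lkr at 64.2 ± 0.841 against 45.5 ± 0.126 CPM. Of the 9 principal cell markers 2 were lower and 1 higher (list adjusted p = 0.778), with salt 2.06-fold lower. Among 28 ion and water transport genes 4 were higher and 5 lower (4 and 6 adjusted over the list alone), and the list did not stand apart (adjusted p = 0.813, with a median of 0.02, a mean of -0.12 and the test pointing up). The potassium channel gene Irk2 stood at 356 ± 15.4 against 184 ± 4.09 CPM.

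The detoxification genes of ZI418N differed from those of SU26 mainly downward. Of 8 insecticide-linked P450 genes 7 were lower and 0 higher, also adjusted over the list alone, with a median log2 fold change of -2.26 (list adjusted p = 2.85e-10; adjusted p = 0.0968 with an estimated correlation). Cyp12d1-d was 54.1-fold lower (5.71 ± 3.77 against 309 ± 46.3 CPM), Cyp12d1-p was 4.1-fold lower (104 ± 14.8 against 424 ± 47.6 CPM) and Cyp6w1 was 8.17-fold lower. Cyp12d1-d and Cyp12d1-p are near-identical copies, so that reads may be split between them in either direction. Of all 71 P450 genes 23 were lower and 11 higher (26 and 11 adjusted over the list alone; list adjusted p = 0.000908; adjusted p = 0.588 with an estimated correlation), with Cyp28a5 13.9-fold lower and Cyp6t1 5.91-fold higher. Glutathione S-transferases were lower in 12 of 29 and higher in 3 (13 and 4 adjusted over the list alone; list adjusted p = 4.05e-05; adjusted p = 0.321 with an estimated correlation), with GstE10 at 152 ± 10.2 against 607 ± 16 CPM. UDP-glycosyltransferases were lower in 9 of 29 and higher in 3 (9 and 4 adjusted over the list alone; list adjusted p = 0.00988; adjusted p = 0.358 with an estimated correlation), with Ugt302E1 11.9-fold lower.

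In all, 2235 genes differed between ZI418N and SU26, 1014 higher and 1221 lower in ZI418N, and 881 by at least 2-fold. The count was 1217 without ZI418N replicate 1, 1391 without ZI418N replicate 2 and 1412 without SU26 replicate 2. It was also 1217 with the level of salivary gland markers, described below, as a covariate. These markers include LysP, at 130 and 17.2 CPM in ZI418N and at most 0.033 CPM in SU26 and SU58. The covariate is thus confounded with the contrasts of ZI418N, and calls can fall for that reason alone, whatever the source of the transcripts.

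The contrast of ZI418N with SU58 set the same African line against the other European line. Insecticide-linked P450 genes were again lower in ZI418N in 7 of 8 and higher in 0 (7 and 1 adjusted over the list alone), with a median log2 fold change of -3.2, and the list's call held with an estimated correlation (adjusted p = 6.85e-20; adjusted p = 0.048 with an estimated correlation). Cyp6a8 was 72.2-fold lower (13.7 ± 4.36 against 989 ± 193 CPM, adjusted p = 3.63e-06), Cyp12d1-p was 7.73-fold lower and Cyp6w1 was 22.1-fold lower. Cyp6d5, outside that list, was 115-fold lower (4.25 ± 1.82 against 487 ± 35.9 CPM, log2 fold change -6.84 ± 0.3, adjusted p = 1.82e-06). Of all 71 P450 genes 28 were lower and 10 higher (33 and 12 adjusted over the list alone; list adjusted p = 7.37e-07; adjusted p = 0.338 with an estimated correlation). UDP-glycosyltransferases were lower in 14 of 29 and higher in 2 (17 and 2 adjusted over the list alone; list adjusted p = 7.83e-07; adjusted p = 0.155 with an estimated correlation), with Ugt302E1 at 2.23 ± 0.378 against 56 ± 4.29 CPM. Of 29 glutathione S-transferases 10 were lower and 4 higher (12 and 5 adjusted over the list alone; list adjusted p = 0.0953), with GstE6 3.72-fold lower and GstE7 7.49-fold higher.

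Outside the detoxification genes, ZI418N exceeded SU58 in spz (92.9-fold), CG11155 (227 ± 15.6 against 3.78 ± 0.131 CPM), Daao2 (38.2-fold) and CG7968 (31.8-fold). It was lower in CG6184 (644-fold), CG1695 (143-fold), phr, which encodes a DNA photolyase (0.183 ± 0.142 against 25 ± 0.348 CPM), tinc (133-fold) and CG4927 (122-fold). Vm26Ab, carried by SU58 replicate 1, was also called (adjusted p = 0.03, from 2.18e-06 to 0.715 over the alternatives). It did not pass without that library (0.715) or without ZI418N replicate 1 or 2 (0.175 and 0.156). Heat shock and Turandot genes were higher in ZI418N in 4 of 18 and lower in 0 (8 and 0 adjusted over the list alone; list adjusted p = 0.000281; adjusted p = 0.714 with an estimated correlation), with Hsp68 at 31.6 ± 10.1 against 2.83 ± 0.223 CPM. Hsp70Bb (79.2 ± 46 against 3.56 ± 0.132 CPM) and its near-identical copy Hsp70Bbb (138 ± 77.5 against 7.52 ± 0.782 CPM) passed with adjusted p of 0.0375 and 0.0383. Their calls ended in 8 alternatives each, among them leaving out any 1 of the ZI418N, SU58 or SU58xZI418N libraries, and their adjusted p reached 0.204 and 0.215. Hsp68 (adjusted p = 0.00518) lost its call without SU58 replicate 1 or 2 (at most 0.06 over the alternatives).

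Stellate cell markers were higher in 3 of 9 and lower in 1 (4 and 1 adjusted over the list alone), with Prip at 212 ± 6.65 against 106 ± 1.28 CPM and the aquaporin gene Drip at 359 ± 17.6 against 197 ± 5.42 CPM, while the bestrophin gene Best2 was 2.18-fold lower. The list's adjusted p was 0.0453 (adjusted p = 0.74 with an estimated correlation), and it ranged up to 0.0762 when single libraries were left out. Only the omission of a ZI418N, or a SU26xSU58, library kept the call. Of 11 hormone and amine receptor genes 1 was higher and 0 lower (list adjusted p = 0.775, with a median of 0.1, a mean of -0.03 and the test pointing up), against 4 higher and 2 lower in the contrast with SU26 (list adjusted p = 0.276). Cytosolic ribosomal protein genes were lower in 6 of 85 and higher in 0 (5 and 0 adjusted over the list alone; list adjusted p = 0.00823; adjusted p = 0.95 with an estimated correlation; up to 0.0577, without SU58 replicate 2). Oxidative phosphorylation genes were lower in 6 of 70 and higher in 0 (1 and 0 adjusted over the list alone; list adjusted p = 0.00839; adjusted p = 0.945 with an estimated correlation; up to 0.0855, without ZI418N replicate 1). The proteasome list had 5 of 34 lower and 0 higher (list adjusted p = 0.295).

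In all, 1573 genes differed between ZI418N and SU58, 705 higher and 868 lower in ZI418N, and 770 by at least 2-fold. The count was 703 and 723 without SU58 replicate 2 and 1, and 853 and 831 without ZI418N replicate 1 and 2. It was 711 with the salivary gland marker level as a covariate, which is confounded with ZI418N as described above.

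Against the mean of both Swedish lines, the genes named for ZI418N were 4 already named above (mthl9, Cyp6d5, Cyp12d1-d and CG17636) and 6 others. The ammonium transporter gene Rh50 stood at 0.127 ± 0.141 CPM in ZI418N against 16.1 ± 8.84 in SU26 and 15.5 ± 0.478 in SU58 (log2 fold change -6.93 ± 0.76, adjusted p = 0.000326). mthl9 was 90.4-fold lower, Cyp6d5 62.5-fold lower, Cyp12d1-d 50.7-fold lower and CG17636 47.2-fold lower. The 5 largest rises among genes with a mean of at least 10 CPM were CG16826 (1470 ± 1010 CPM in ZI418N), whe (501 ± 85), lcs (148 ± 63.4), LysP, a lysozyme gene (73.8 ± 80.1), and CG34212 (73.7 ± 24.7), each below 1 CPM in both Swedish lines. The same 5 genes differed between replicates within hybrids. CG16826 stood at 3080 and 2.03 CPM in SU58xZI418N replicates 1 and 2, at 0.269 and 2450 CPM in SU26xZI418N, and at 0.185 and 651 CPM in SU26xSU58, which has no ZI418N parent. Their adjusted p lay between 0.0189 and 0.0448, reached 0.275 (LysP) to 0.766 (CG34212) over the alternatives, and was lost without any single SU26 or SU58 library or without ZI418N replicate 1. Without ZI418N replicate 2 the calls of CG16826, whe, lcs and CG34212 were lost too.

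**Figure D2:**
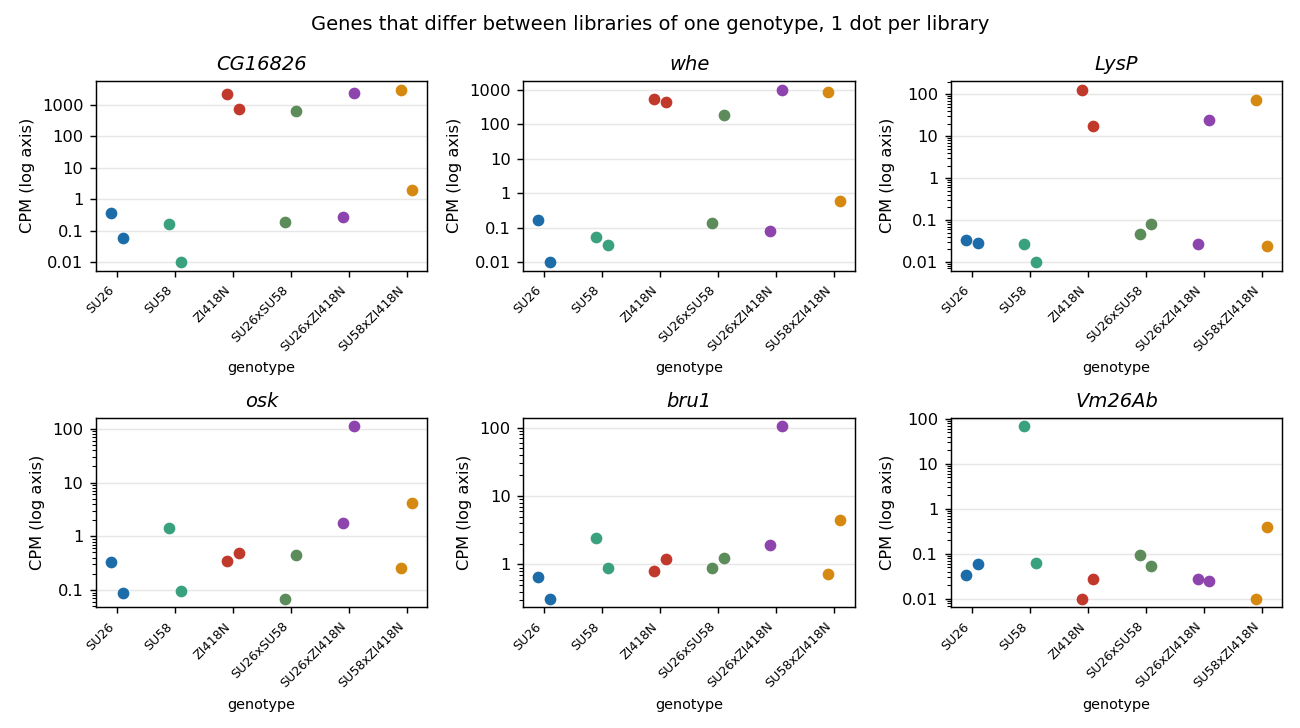
CPM on a log axis for 6 genes, 1 dot per library, by genotype, with values of 0 drawn at 0.01. CG16826 and whe are high in both ZI418N libraries and in 1 library of each hybrid, and osk and bru1 are high in SU26xZI418N replicate 2 (111 and 104 CPM).

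The 4 genes with differences between African and other populations in earlier studies had mixed behaviour. CHKov1 (FBgn0045761) was 2.01-fold higher in ZI418N than in the Swedish mean (78.2 ± 3.76 against 38.9 ± 0.213 in SU26 and 39.1 ± 0.0994 CPM in SU58, adjusted p = 9.23e-05). Cyp6g1 (FBgn0025454), linked to DDT resistance, was 1.76-fold lower in ZI418N (5270 ± 399 against 7690 ± 1320 and 11300 ± 986 CPM, adjusted p = 0.00281; from 3.65e-08 to 0.075 over the alternatives, 0.075 with the salivary gland marker covariate). fiz was 1.37-fold lower (2600 ± 153 against 3340 ± 633 and 3770 ± 8.65 CPM, adjusted p = 0.0207), and its adjusted p ranged up to 0.178, with the call lost without any of the SU58 or ZI418N libraries. MtnA, a metallothionein gene, stood at 734 ± 514 CPM in ZI418N, 838 ± 323 in SU26 and 1400 ± 252 in SU58, within the spread between replicates (adjusted p = 0.443). The list had 1 higher and 2 lower, as when adjusted over the list alone (list adjusted p = 0.895). As placed by the Ensembl annotation of BDGP6, CHKov1 lies at 3R 25323156 to 25329316, Cyp6g1 at 2R 12185667 to 12188431, fiz at X 14906334 to 14909708 and MtnA at 3R 9783407 to 9784370. The build behind the counts is not given in the sources used here.

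By list, the insecticide-linked P450 genes were lower in 7 of 8 and higher in 0 (7 and 1 adjusted over the list alone; list adjusted p = 3.36e-16; adjusted p = 0.048 with an estimated correlation). UDP-glycosyltransferases had 13 lower and 1 higher, glutathione S-transferases 13 lower and 5 higher, oxidative phosphorylation 41 lower and 0 higher, and the proteasome 17 lower and 1 higher. Adjusted over the list alone these were 15 and 3, 14 and 6, 52 and 1, and 22 and 1. The adjusted p of those lists was 7.24e-05, 0.00172, 2.9e-08 and 2.87e-05 (adjusted p = 0.219, 0.433, 0.734 and 0.734 with an estimated correlation). Metallothionein and antioxidant genes had 7 lower and 0 higher (9 and 1 adjusted over the list alone; list adjusted p = 0.00207; adjusted p = 0.335 with an estimated correlation). Stellate cell markers had 4 higher and 1 lower (6 and 1 adjusted over the list alone; list adjusted p = 0.00681; adjusted p = 0.622 with an estimated correlation). Heat shock and Turandot genes had 4 higher and 0 lower (list adjusted p = 0.00854; adjusted p = 0.799 with an estimated correlation), which was 0.0556 without ZI418N replicate 2, the library with the list's highest sum (4609 CPM). In the contrast with SU58 camera did not call the proteasome, glutathione S-transferase or metallothionein and antioxidant lists (adjusted p = 0.295, 0.0953 and 0.181). In that with SU26 it did not call the heat shock list (adjusted p = 0.482). For these lists the contrast with the Swedish mean does not show a difference from both lines. For other tissues the list tests did not pass in this contrast. The adjusted p was 0.813 for gut digestive enzymes, 0.633 for fat body, 0.63 for eggshell and germ line, 0.434 for muscle, 0.917 for hemocytes and 0.968 for neurons and photoreceptors. The test of the gut list pointed down although its median of 0.2 and mean of 0.88 were positive, and that of the neuron list pointed up although its median and mean were -0.11 and -0.26. Purine, tryptophan and eye pigment genes (2 higher, 4 lower of 27), the circadian clock (2 higher, 0 lower of 9) and V-ATPase subunits (0 and 0 of 22) did not pass either (adjusted p = 0.578, 0.295 and 0.973). The test of the V-ATPase list pointed up although its mean was -0.09. In all, 2027 genes differed, 974 higher and 1053 lower in ZI418N, with 986 without ZI418N replicate 1, 1068 without its replicate 2, 1273 without SU58 replicate 2 and 827 with the salivary gland marker covariate.

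**Figure D3:**
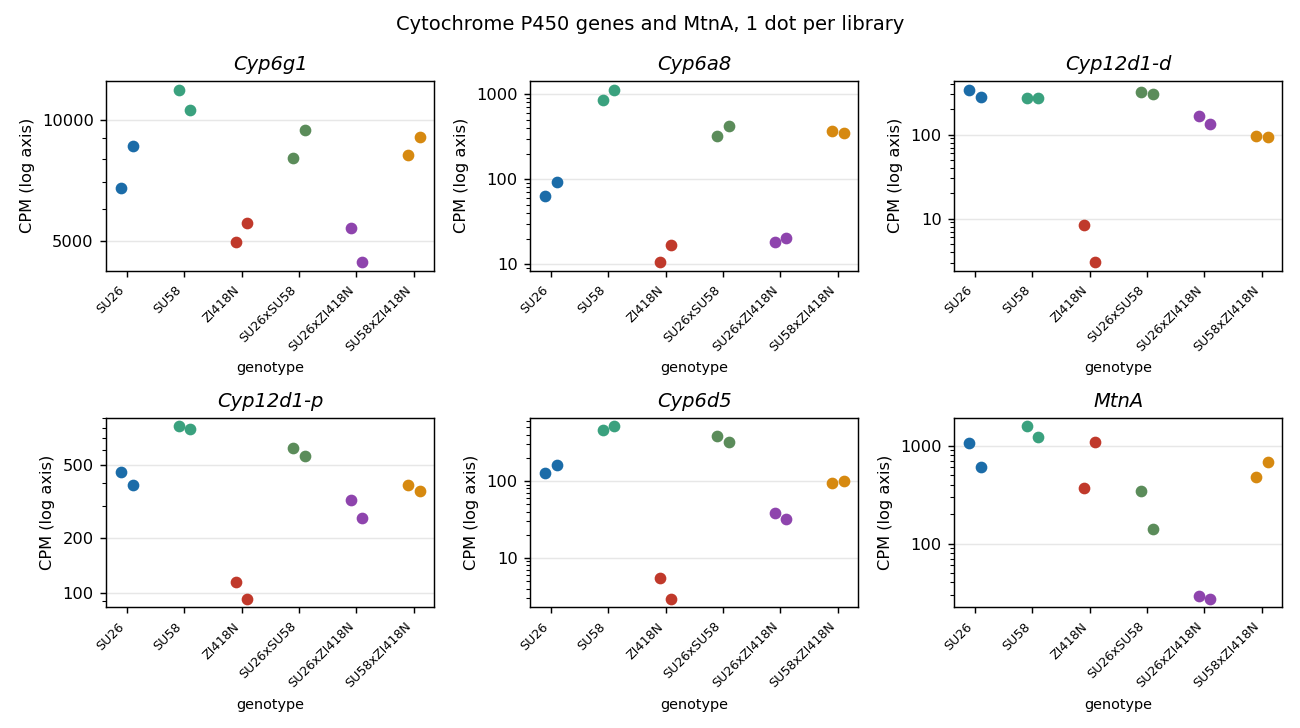
CPM on a log axis for 5 cytochrome P450 genes and the metallothionein gene MtnA, 1 dot per library, by genotype. Cyp6d5 lies at 2.96 and 5.53 CPM in ZI418N and at 462 and 513 CPM in SU58, and MtnA at 29.3 and 27.3 CPM in SU26xZI418N.

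The comparison of each F1 with its parents asked how expression of parental differences is inherited. Among genes differing at least 2-fold between the parents, the median F1 lay nearer to the higher parent on the log2 scale, though not where SU26 was the higher parent. The median position, 0 for the lower and 1 for the higher parent, was 0.61 ± 0.022 (SD of the replicates' medians, n = 2) for the 644 genes of SU26xSU58, 0.56 ± 0.042 for the 881 genes of SU26xZI418N and 0.64 ± 0.008 for the 770 genes of SU58xZI418N. Where SU26 was the higher parent the median was 0.5 in SU26xSU58 (297 genes) and 0.45 in SU26xZI418N (470 genes), against 0.66 in both where the other parent was higher (347 and 411 genes). In SU58xZI418N it was 0.63 where SU58 was higher and 0.64 where ZI418N was. An equal mixture of both parents' CPM has median positions of 0.65, 0.65 and 0.66. The F1 lay between its parents in 93.5%, 83.5% and 94.4% of the genes. In SU26xSU58 372 genes (57.8%) did not differ from either parent by test, 158 differed from the lower parent only, 79 from the higher parent only and 35 from both while lying between them. In SU26xZI418N the corresponding numbers were 248, 277, 239 and 116, and in SU58xZI418N they were 422, 215, 42 and 90. In each of the latter hybrids 1 gene differed from each parent, tested on its own, and lay outside both.

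**Figure D4:**
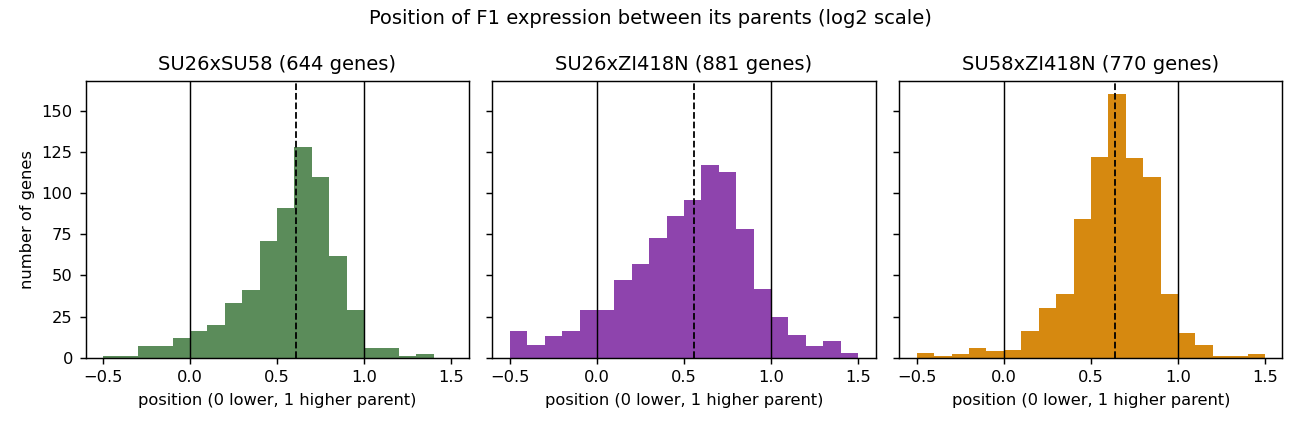
Histograms of the position of F1 expression between its parents on the log2 scale, 0 for the lower and 1 for the higher parent, for genes differing at least 2-fold between the parents; the vertical axis counts genes, values outside -0.5 to 1.5 are gathered in the end bins and the dashed line is the median. The medians are 0.61, 0.56 and 0.64.

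Single genes departed from the log2 mid-parent in each cross. In SU26xSU58 these were 10 genes, all higher, and those with a mean of at least 10 CPM over the F1 and its parents were led by CG1695 (24.9 ± 7.44 CPM in the F1), CG12910 (33.2 ± 3.11), Ldsdh1 (21.4 ± 2.89), CG11155 (76.5 ± 8.31) and CG9981 (24.2 ± 6.32). Set beside the parents' mean in CPM, CG11155 reached 0.93 of it, CG1695 0.91, CG9981 0.78, CG12910 1.36 and Ldsdh1 1.9. Of the 10 genes 8 lay within 1.5-fold of the parents' mean in CPM. The adjusted p was 9.93e-05 for CG11155, 0.000733 for Ldsdh1 and 0.00097 for CG12910, which held in every alternative. It was 0.0199 for CG1695 and 0.0146 for CG9981, which rose to at most 0.199 and 0.134 and were lost without any of the SU26 or SU58 libraries. CG9981 was also lost without SU26xSU58 replicate 1, and CG1695 without either SU26xSU58 or either SU58xZI418N library. The count of 10 became 4 without SU58 replicate 1 or 2, 5 and 6 without SU26xSU58 replicate 1 and 2, and 19 and 20 without SU26xZI418N replicate 1 and 2.

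In SU58xZI418N 36 genes departed from the mid-parent, 35 higher and 1 lower. CG11155 stood at 115 ± 4.03 CPM, equal to the parents' mean of 115 CPM, mthl9 at 33.4 ± 0.914 CPM (0.81 of the mean) and CG7402 at 48.2 ± 4.11 CPM (1.41 of the mean). CG4830 exceeded both parents, at 21 ± 3.92 CPM against 3.4 ± 0.444 in SU58 and 9.26 ± 1.13 in ZI418N (log2 1.9 ± 0.2 above the mid-parent, adjusted p = 0.00357; 7.83e-12 to 0.0698 over the alternatives, 0.0698 without SU58xZI418N replicate 2). Rh50 stood at 17.4 ± 11.8 CPM (adjusted p = 0.0199, at most 0.137 over the alternatives), and its call was lost without SU58xZI418N replicate 1 or any SU58, ZI418N or SU26xSU58 library. The gene below the mid-parent was chinmo, which encodes a BTB zinc finger protein, at 10.3 ± 1.43 CPM against 16.8 ± 1.49 and 47.3 ± 8.92 CPM (adjusted p = 0.00357; 3.4e-13 to 0.0835 over the alternatives, 0.0835 without SU58xZI418N replicate 1). Of the 35 higher genes 25 lay within 1.5-fold of the parents' mean in CPM. The count was 19 and 18 without SU58 replicate 1 and 2, and 16 and 13 without SU58xZI418N replicate 1 and 2.

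In SU26xZI418N 465 genes departed from the mid-parent, 306 higher and 159 lower, and those higher with a mean of at least 10 CPM were led by transcripts of the female germ line. Pxt, BicC, osk, Marf1 and yl stood at 38.6 ± 53.9, 66.5 ± 90.9, 56.6 ± 77.5, 64.8 ± 89.6 and 74.2 ± 99.4 CPM, each with an SD above its mean because replicate 2 carried them. Their adjusted p lay between 0.0416 and 0.0461 and rose to between 0.464 and 0.684 over the alternatives, and their calls were lost without any single library other than SU26xZI418N replicate 1. BicC shares 94.8% of its exon length with an overlapping gene and osk 84.1%. The genes below the mid-parent at a mean of at least 10 CPM were led by MtnA, at 28.3 ± 1.43 CPM against 838 ± 323 in SU26 and 734 ± 514 in ZI418N (log2 -4.79 ± 0.6, adjusted p = 0.0113). MtnA ranged from 2.71e-16 to 0.189 over the alternatives and was 0.0929 without SU26xZI418N replicate 2. Idgf1, an imaginal disc growth factor gene (3.82 ± 1.28 CPM), MFS12 (51 ± 3.83), CG5399 (36.1 ± 1.82) and stv (15.8 ± 2.33) followed. Their adjusted p of 0.0319, 0.0444, 0.024 and 0.0444 reached 0.295, 0.266, 0.243 and 0.454 over the alternatives, and none of the 4 passed without SU26xZI418N replicate 2 or without SU26 replicate 2. Idgf1 did not pass without any 1 of the SU58, SU26xSU58 or SU58xZI418N libraries either, MFS12 passed only without SU26xZI418N replicate 1, and stv only without that library or a SU26xSU58 library.

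The count of 465 depended on single libraries of every genotype. It was 25 without SU26xZI418N replicate 2 and 1773 without its replicate 1. It was 84 (34 higher and 50 lower) and 30 without SU26 replicate 1 and 2, 38 without SU58 replicate 1 or 2, 81 and 36 without ZI418N replicate 1 and 2, 51 without SU26xSU58 replicate 1 or 2, and 48 without SU58xZI418N replicate 1 or 2.

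No gene lay outside both parents by edgeR's test in any cross after adjustment. At an unadjusted p under 0.05 there were 33 genes in SU26xSU58, 822 in SU26xZI418N and 41 in SU58xZI418N. DESeq2 called 1, 172 and 1 genes, and 44, 825 and 32 at an unadjusted p under 0.05. Without SU26xZI418N replicate 1, which leaves the library with germ line transcripts as the only one of its genotype, edgeR called 872 genes in that cross.

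Differences between hybrids that share a parent followed those between the parents they do not share. SU26xZI418N and SU26xSU58 differed in 440 genes (160 higher and 280 lower in SU26xZI418N, but 600 and 517 with DESeq2 and 1386 and 517 without SU26xZI418N replicate 1). Of the 1573 genes that differed between ZI418N and SU58, 93.1% had the same sign between these hybrids, with a median ratio of 0.48 of the parental log2 difference, and 390 of 391 genes called in both contrasts had the same direction (38.3 if the lists were independent). SU58xZI418N and SU26xSU58 differed in 269 genes (151 higher, 118 lower, but 55 and 56 without SU26xSU58 replicate 2). Of the genes that differed between ZI418N and SU26 88.9% had the same sign, with a median ratio of 0.35, and 257 of 258 genes called in both had the same direction (31.9 if independent). SU58xZI418N and SU26xZI418N differed in 192 genes (147 higher, 45 lower, but 311 and 319 with DESeq2 and 315 and 1222 without SU26xZI418N replicate 1). Of the genes that differed between SU58 and SU26 72.4% had the same sign, with a median ratio of 0.23, and 159 of 161 genes called in both had the same direction (16.2 if independent). Over all genes the shares of the same sign were 67.4%, 70.1% and 54.9% and the correlations 0.4, 0.65 and 0.28. Each such pair of contrasts has no library in common.

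For SU26xZI418N against SU26xSU58, the count of 440 was 1903 without SU26xZI418N replicate 1 and 196 without its replicate 2. It was 209 and 156 without SU26xSU58 replicate 1 and 2, and 247 and 246 without SU58 replicate 1 and 2. For SU58xZI418N against SU26xSU58, the count of 269 was 128 and 111 without SU26xSU58 replicate 1 and 2, and 92 and 103 without SU58xZI418N replicate 1 and 2. For SU58xZI418N against SU26xZI418N, the count of 192 was 1537 and 82 without SU26xZI418N replicate 1 and 2, 66 and 57 without SU58xZI418N replicate 1 and 2, and 100 and 94 without SU58 replicate 1 and 2.

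Hybrids as a group differed from parents as a group in 79 genes, 47 higher and 32 lower, but 152 and 194 with DESeq2. MtnA was 6.01-fold lower in the hybrids, at 241 ± 141 CPM in SU26xSU58, 28.3 ± 1.43 in SU26xZI418N and 582 ± 151 in SU58xZI418N (adjusted p = 0.00787). chinmo was 2.19-fold lower and Idgf1 4.2-fold lower, and the higher genes included mthl9 (2.36-fold), CG7402 (2.32-fold), CG11155 (2.31-fold) and CG12910 (2.29-fold). These folds compare means on the log scale. In CPM, mthl9 stood at 92.3, 36 and 33.4 in SU26xSU58, SU26xZI418N and SU58xZI418N against 102, 81.9 and 1.01 in SU26, SU58 and ZI418N, and CG11155 at 76.5, 193 and 115 against 160, 3.78 and 227. With the counts of each genotype summed, the log2 fold changes of mthl9 and CG11155 turned to -0.19 and -0.03, and those of CG7402 and CG12910 became 0.41 and 0.39. Rh50 (4.91-fold higher), MFS12 (2.91-fold lower) and CG5399 (2.22-fold lower) passed with adjusted p of 0.0294, 0.0472 and 0.0401. The calls of these 3 genes, and that of Idgf1 (adjusted p = 0.0209), were lost without SU26xSU58 replicate 1 or 2, SU58 replicate 2 or SU26xZI418N replicate 2. Rh50 also lost its call without SU26 replicate 1, SU58 replicate 1 or either ZI418N library, MFS12 without any 1 of the SU26, ZI418N or SU58xZI418N libraries, CG5399 without SU58 replicate 1 or any 1 of the SU26 or SU58xZI418N libraries, and Idgf1 without either SU58xZI418N library. In that fit, with 3 hybrids against 3 parental lines, edgeR called 0 genes (139 at an unadjusted p under 0.05, and 346 by DESeq2 on the libraries) and each of these genes had an adjusted p of 1. The count of 79 was 790 without SU26xZI418N replicate 1 and 28 without SU58 replicate 2. It was 40 without SU26 replicate 2 or SU58 replicate 1, 33 and 45 without SU26xSU58 replicate 1 and 2, and 35 and 41 without SU58xZI418N replicate 1 and 2.

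Several lists were lower in the hybrids by list test, with few or no single genes called. Heat shock and Turandot genes had 0 of 18 called (0 higher and 10 lower adjusted over the list alone), with a median log2 fold change of -0.91 (list adjusted p = 2.21e-11; adjusted p = 0.338 with an estimated correlation). The list's median CPM was high in 3 parental libraries, SU26 replicate 2 (67.1) and ZI418N (46.6 and 63.6), while SU26 replicate 1 (5.39) and SU58 (7.48 and 6.74) lay within the range of the hybrids, 3.01 to 19.6. Hemocyte genes had 0 of 10 called (0 and 5 adjusted over the list alone; median -0.92; list adjusted p = 1.98e-07; adjusted p = 0.313 with an estimated correlation). Oxidative phosphorylation and proteasome genes had 0 called, with medians of -0.1 and -0.09 (list adjusted p = 4.33e-08 and 3.99e-06; adjusted p = 0.734 and 0.721 with an estimated correlation). SU26 carried both differences. The median CPM of oxidative phosphorylation was 194 and 184 in SU26, 135 to 165 in SU58 and ZI418N and 136 to 168 in the hybrids. That of the proteasome was 104 and 107 in SU26, 73.5 to 76.8 in SU58 and ZI418N and higher than those, 77.5 to 83.5, in the hybrids. The P450 list, next, rose on the log scale but not in CPM (sums of 12850 to 20430 in hybrids, 13110 to 23520 in parents). Cytochrome P450 genes were higher in 4 of 71 and lower in 2 (17 and 4 adjusted over the list alone; list adjusted p = 0.000911; adjusted p = 0.588 with an estimated correlation; 0.505 without SU26xZI418N replicate 1). Gut digestive enzymes were higher in 1 of 31 and lower in 0 (3 and 1 adjusted over the list alone; list adjusted p = 0.00913; adjusted p = 0.734 with an estimated correlation; up to 0.813, lost without SU26 replicate 2, ZI418N replicate 1, SU26xSU58 replicate 2 or SU26xZI418N replicate 2).

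Calls between parental lines were not concentrated on any of the arms tested, X, 2L, 2R, 3L and 3R (20 Fisher's exact tests, two-sided, lowest adjusted p = 0.22, for arm X in SU58 against SU26, with 234 of 1518 genes called).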

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

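The comparison of offsets between crosses and the tests of ovary, a mislabelled sample, the hybrid genotype, salivary gland, midgut, the ZI418N genotype, metal-responsive transcription and a line variant were chosen only after the results were seen. For 6 of them the condition or the markers were revised once more after a first value had been seen. The test for a mislabelled sample first asked for transcripts private to SU26 at 10% of their SU26 level, which neither SU26xZI418N library reached (medians 4.5% and 3.6%). The salivary gland test first counted against that source before markers at the floor or present everywhere were set aside, the metal-responsive test gained a condition on counting error, and the ovary test lost 4 markers already looked at (swa, mtrm, gnu and bru1) and later orb and otu, which are among the genes called off the mid-parent. The tests of midgut and of the hybrid genotype first counted against these, before genes near the floor and the fall of the count without other libraries were taken into account.

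The F1 offset from the log2 mid-parent differed between crosses in a small number of genes, by edgeR's test of the difference itself. Between SU26xZI418N and SU26xSU58 it differed in 14 genes, 7 higher and 7 lower in SU26xZI418N, and 8 of them passed without SU26xZI418N replicate 2. Between SU58xZI418N and SU26xSU58 it differed in 9 genes, 7 higher and 2 lower, with 10 genes without that library, 9 of them shared. Between SU58xZI418N and SU26xZI418N it differed in 4 genes, 3 higher and 1 lower, with 2 without that library, both shared. The 4 genes were CG11155 (log2 difference 1.96 ± 0.11 SE, adjusted p = 0.000279), CG12910 (-2.09 ± 0.2), Ldsdh1 (1.71 ± 0.17) and Cyp6a8 (2.38 ± 0.29, adjusted p = 0.0388), and Ldsdh1 and Cyp6a8 did not pass without SU26xZI418N replicate 2. In each of the 4 genes the parents of one cross differ far more than those of the other. CG11155 stands at 3.78 CPM in SU58 against 160 in SU26 and 227 in ZI418N, and Cyp6a8 at 989 CPM in SU58 against 78.7 and 13.7. An F1 at the CPM mean of its parents lies farther above the log2 mid-parent the more the parents differ. Such F1s would give 1.96 for CG11155, but 1.02 for Ldsdh1 and 1.61 for Cyp6a8. Over the 27 differences called in the 3 comparisons, 25 had such a value. It was at least 0.5 of the observed one in 19, smaller in 4 and of opposite sign in 2. The observed difference lay more than 2 SE from that value in 19 of the 25. These differences were chosen because they were called, and the value was given no error of its own. The count beyond 2 SE therefore cannot decide whether the F1s lie at the CPM mean. mthl9, CG16800, CG8539, CG7402 and chinmo differed in both comparisons with SU26xSU58 (mthl9 by 1.81 and 1.86, CG16800 by 4.54 and 4.31, CG8539 by 0.93 and 1.01, CG7402 by 1.4 and 1.49, chinmo by -2.04 and -1.5). CG16800 stood at 0 CPM in ZI418N, so the size of its differences depends on how a level of 0 is treated on the log scale. CG8539 and CG7402 did not pass between SU26xZI418N and SU26xSU58 without SU26xZI418N replicate 2. For chinmo, F1s at the CPM mean would give 0.49 and -0.01.

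SU26xZI418N replicate 2 stood apart from its replicate 1, and RNA from ovary is a candidate source. Of 5 ovary transcripts neither looked at before nor called off the mid-parent in this cross (aub, cup, exu, png and plu, the last below the filter on low counts), 5 were highest in this library among the 12, with cup at 69.3 CPM against at most 14.6 CPM elsewhere. Both libraries are labelled with the same hybrid genotype, so genotype alone cannot account for the difference between them. Whether it moved the 465 genes off the mid-parent is a separate question that the replicates leave undecided. Genes called above the mid-parent lay a median log2 distance of 2.26 farther from it in replicate 2 (quartiles 0.18 to 4.93). Of these 306 genes 248 were farther from it there. Those called below it lay only 0.11 farther (quartiles -0.01 to 0.24), and 117 of 159 were farther there. A mislabelled sample is argued against by transcripts private to 1 parental line, since those of SU58 had a median of 0.1% of their SU58 level here (phr, Marf1 and Pxt were exceptions at 21.8%, 275.8% and 1121.7%), those of ZI418N other than LysP had 23.6% to 62.5%, and 5 of 5 of SU26 were above every library without a SU26 parent. How ovary RNA would have come into the library was not tested.

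CG16826, whe, lcs, CG34212 and LysP were high in both ZI418N libraries and in SU26xZI418N replicate 2 and SU58xZI418N replicate 1, and all but LysP also in SU26xSU58 replicate 2. The ZI418N genotype as the whole cause is argued against by CG16826 at 651 CPM in SU26xSU58 replicate 2, which has no ZI418N parent, and by a 1520-fold ratio between the SU58xZI418N replicates. RNA from midgut cannot be told apart from other sources, since 15 trypsin and Jonah protease genes had a median log2 ratio of -0.06 between SU58xZI418N replicates 1 and 2 but lay near the floor (median 0.398 CPM in these 5 libraries), and the total of the gut list was 128 CPM or more in the 5 and at most 90.1 CPM in the other 7, or 41.8 to 110 CPM and 49.6 to 89.3 CPM without LysP and Mal-B1, chosen after their values were seen. RNA from salivary gland cannot be told apart from other sources, since 0 of 5 markers not looked at before were higher in each of these 5 libraries than in each other library, but only 1 was usable, with fkh at 282 to 456 CPM everywhere and eyg and toe at most at 1.14 and 0.511 CPM. A difference between ZI418N and the Swedish lines themselves stays open, since the adjusted p of 0.0189 to 0.0448 for these genes was lost without single libraries.

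MtnA was low in both SU26xZI418N libraries, at 29.3 and 27.3 CPM against 370 CPM or more in the libraries of its parents. A line variant against the reference is argued against, because the highest F1 library stood at 29.3 CPM and no parental library was near it, and RNA from ovary in replicate 2 is argued against because MtnA in replicate 1 stood at 7.91% of the lowest parental library. Low activity of metal-responsive transcription cannot be told apart. Of 3 other measured metallothionein genes, 1 was lower than in all 4 parental libraries by more than counting error (MtnC, at 0.484 and 0.647 CPM against 1.76 CPM or more). MtnE was lower but within counting error, and MtnD was not lower. By edgeR's test MtnC and MtnE were also called below the mid-parent in this cross (log2 -2.65 and -2.36), MtnE at a mean of 0.104 CPM in the F1. The offset of MtnA was not called different from that in the other crosses (log2 difference from SU26xSU58 -2.63, adjusted p = 0.357, and of SU58xZI418N from SU26xZI418N 3.99, adjusted p = 0.113). An effect of this cross was not called by that test and stays open.

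For the 79 genes that differed between hybrids and parents, the 6 genotypes make 10 splits of 3 against 3. These are too few for a share under 0.05, and 10 of the 10 gave at least as many genes, the real split included. The splits are not exchangeable. Where F1s lie at their log2 mid-parent, differences between parental lines cancel in hybrids against parents but stay in every other split. The other splits, with 290 to 2391 genes, thus contain parental differences, and their counts do not bear on the 79 genes. The highest, 2391, set genotypes with against those without a ZI418N parent.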

How the results depend on the processing

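The alternative that leaves out SU58 replicate 1 and SU26xZI418N replicate 2 was chosen only after the data were seen. So was the salivary gland marker level as a covariate. These 2 libraries had the highest sums of the eggshell and germ line list (421.3 and 182.8 CPM). Below they are called both libraries with eggshell or ovary transcripts, but other libraries carried less of them and stayed in. Among those was SU26 replicate 1, with a sum of 63.25 CPM. Of 266 counts under an alternative 174 were within 1.5 times the count in the report, 72 were smaller and 20 larger. Of 63 median positions of F1s 53 moved by less than the SD of the replicates. Of 4916 values of named genes 4304 stayed on their side of the threshold with no called value changing direction, 602 lost their call, 2 gained it and 8 reversed. Of 2000 list tests 1870 stayed on their side of the threshold, 97 lost their call and 33 gained one. With 2 libraries per genotype, leaving out 1 moves many counts, and a lone library is then assumed to vary like the others. Except where fewer libraries or genes make the alternative, the cause was not tested.

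With an estimated correlation 0 comparisons were called for the lists of V-ATPase, organic solute and metal transport, cytochrome P450, glutathione S-transferases, UDP-glycosyltransferases, antimicrobial peptides, heat shock proteins, metallothioneins, ribosomal proteins, oxidative phosphorylation, the proteasome, African differences, principal cells, stellate cells, gut, muscle and hemocytes, and 2 for insecticide-linked cytochrome P450.

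With no filter on low counts 22 genes in SU26xSU58 and 821 in SU26xZI418N were off the mid-parent, 1 lay outside both parents in SU26xZI418N, the clock list was called in 1 comparison, and the African, gut and muscle lists in 0. The list of UDP-glycosyltransferases in SU58 vs SU26 then lost its call. With DESeq2 the genes off the mid-parent were 69, 1294 and 85 in SU26xSU58, SU26xZI418N and SU58xZI418N, and those outside both parents 1, 172 and 1. DESeq2 found 1117 genes between SU26xZI418N and SU26xSU58, 508 between SU58xZI418N and SU26xSU58, 630 between SU58xZI418N and SU26xZI418N, and 346 between hybrids and parents.

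With the replicate number as a replicate block 68 genes were off the mid-parent in SU26xZI418N, and the V-ATPase and principal cell lists were called in 0 comparisons. The stellate cell list lost its call between ZI418N and SU58 (adjusted p = 0.067). Deviations from genotype means correlated at -0.22 to 0.32 between libraries of one replicate number over 15 pairs of genotypes, 4 above 0.1 and 3 below -0.1, so no shift common to the numbers was seen.

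With a minimum of 1.5-fold between parents the median positions were 0.57, 0.52 and 0.61 in SU26xSU58, SU26xZI418N and SU58xZI418N, and with a minimum of 4-fold 0.64, 0.61 and 0.69. With only the F1 and its parents in the fit 16 genes were off the mid-parent in SU26xZI418N. With only hybrid libraries in the fit, which leaves fewer libraries for the spread, 140 genes differed between SU26xZI418N and SU26xSU58, 67 between SU58xZI418N and SU26xSU58, and 21 between SU58xZI418N and SU26xZI418N. With counts summed per genotype edgeR called 0 genes between hybrids and parents (139 at an unadjusted p under 0.05, and 346 by DESeq2 on the libraries), and mthl9 and CG11155 had the opposite sign there (log2 -0.19 and -0.03, adjusted p of 1 each).

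Without both libraries with eggshell or ovary transcripts 618 genes differed between SU58 and SU26 and 860 between ZI418N and SU58, 6 and 14 were off the mid-parent in SU26xSU58 and SU26xZI418N, 118 differed between SU26xZI418N and SU26xSU58, 46 between SU58xZI418N and SU26xZI418N, and 31 between hybrids and parents. There the direction turned for Vml in SU58 vs SU26 (adjusted p = 0.669), Vm26Aa in SU58 vs SU26 (0.723) and Vml in ZI418N vs SU58 (0.935), since SU58 replicate 1 was the only library with more than 1 CPM of either transcript. With the salivary gland marker level as a covariate 1217 genes differed between ZI418N and SU26 and 711 between ZI418N and SU58. Between ZI418N and the mean of SU26 and SU58 827 differed, between SU26xZI418N and SU26xSU58 276, and between hybrids and parents 43. In SU26xZI418N 62 were off the mid-parent. The marker level is high in both ZI418N libraries and confounded with the contrasts of that line, so their lower counts do not bear on the source of the transcripts.

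With 1 library left out at a time the count between SU58 and SU26 ranged from 492 (without SU58 replicate 1) to 1939, between ZI418N and SU26 from 1217 (without ZI418N replicate 1) to 2565, between ZI418N and SU58 from 703 (without SU58 replicate 2) to 1877, and between ZI418N and the mean of SU26 and SU58 from 986 (without ZI418N replicate 1) to 2389, each highest without SU26xZI418N replicate 2. Off the mid-parent were 4 (without either SU58 library) to 20 genes in SU26xSU58, 25 (without SU26xZI418N replicate 2) to 1773 (without its replicate 1) in SU26xZI418N and 13 (without SU58xZI418N replicate 2) to 44 in SU58xZI418N, and outside both parents 0 to 872 (without SU26xZI418N replicate 1) in SU26xZI418N. Between SU26xZI418N and SU26xSU58 156 (without SU26xSU58 replicate 2) to 1903 genes differed, between SU58xZI418N and SU26xZI418N 57 (without SU58xZI418N replicate 2) to 1537, and between hybrids and parents 28 (without SU58 replicate 2) to 790, each highest without SU26xZI418N replicate 1, and between SU58xZI418N and SU26xSU58 92 (without SU58xZI418N replicate 1) to 333. More genes were then higher than lower between SU58 and SU26 without SU58 replicate 1 (284 and 208) or 2 (298 and 281), and between ZI418N and the Swedish mean without ZI418N replicate 1 (497 and 489), against more lower with all libraries. Median positions ranged from 0.59 to 0.63 in SU26xSU58 and from 0.63 to 0.65 in SU58xZI418N. The adjusted p ranged from 0.00063 to 0.691 for Vml in SU58 vs SU26, from 0.00253 to 0.738 for Vm26Aa in SU58 vs SU26 and from 0.000232 to 0.947 for Vml in ZI418N vs SU58, the direction turning without SU58 replicate 1. The lists of V-ATPase, ion and water transport, African differences, principal cells, gut and muscle were called in 0 to 1 comparisons, and fat body and eggshell in 0 to 2.

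Small changes were seldom recovered in the simulation (6% at 1.5-fold, as above), which did not vary depth.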

Other observations

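The grouping of transcripts by the parent with the high level, and their levels in the hybrids, were looked at only after the results were seen, and no tests were made of them.

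Some transcripts stood at 5 CPM or more in 1 of the parental lines and over 16-fold above both others there. Leaving aside 10 genes that were high in the 5 libraries with CG16826 above 10 CPM, there were 5 of these in SU26, 15 in SU58 and 5 in ZI418N. The genes left aside were over 2-fold higher in each of those 5 libraries than in each other library. Among them CG16826, whe, lcs and CG34212 meet the rule for ZI418N, so its count would be higher with them. Levels below are percentages of the way from the mean of the other parental lines to that parent. The SU58 transcripts had medians of 45.4% and 29.1% in the SU26xSU58 libraries and of 39.6% and 41.3% in SU58xZI418N. The ZI418N transcripts include LysP, which does not follow the genotype (0% and 32.5% in SU26xZI418N, 100.5% and 0% in SU58xZI418N), and the other 4 lay between 18.1% and 81.8% in SU26xZI418N and between 15.5% and 72.2% in SU58xZI418N. The SU26 transcripts had lower medians, of 11% and 10.3% in SU26xSU58 and of 4.5% and 3.6% in SU26xZI418N. These 5 ranged widely, from 0.3% to 74.6% in SU26xSU58 and from -0.2% to 70.5% in SU26xZI418N. Jhe, for 1, stood at 38.4% and 33.1% in SU26xSU58 and at 28.2% and 22.3% in SU26xZI418N. The genes named here were chosen after their values were seen. The photolyase gene phr of SU58 stood at 53.9% and 52.8% of its SU58 level in the SU26xSU58 libraries and at 55.1% and 55% in SU58xZI418N. CG15772 of SU58 stood at 67.1% and 67.5% in SU26xSU58 and at 59.6% and 61% in SU58xZI418N. CG12910 of SU26 stood at 74.6% and 64.9% in SU26xSU58 and at 70.5% and 60.5% in SU26xZI418N. Daao2 of ZI418N stood at 31.2% in both SU26xZI418N libraries and at 47.3% and 48.2% in SU58xZI418N.

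A few stayed far below that. CG6184, with 38.3 CPM in SU58, stood at 1.3% and 1.4% of that level in SU26xSU58 and at 1.9% and 5.4% in SU58xZI418N. The potassium channel gene Elk of SU26 (15.5 CPM) stood at 6.3% and 5.8% in SU26xSU58 and at 4.5% and 3.3% in SU26xZI418N. CG4927 of SU58 (36.5 CPM) stood at 38.8% and 24.5% in SU26xSU58 and at 7.1% and 6.7% in SU58xZI418N, so that its level differed between crosses with a common parent. Its offset from the mid-parent was not called different between these crosses.

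A pair of genes, chosen after their values were seen, differed between replicates of some genotypes. The clock gene tim stood at 930 and 29.6 CPM in the SU26 libraries and at 18 and 382 CPM in those of SU58xZI418N, but at 394 and 306 CPM in SU26xZI418N. Hsp70Aa stood at 42.7 and 416 CPM in SU26 and at 171 and 429 CPM in ZI418N, but at 40.7 and 41 CPM in SU58. The times of dissection are not given in the sources used here.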
